A study of Homo sapiens with 6 samples.

How the data were processed

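RNA was measured on 6 one-colour Affymetrix human expression arrays, 1 array per tumour sample. The samples were subcutaneous tumours of U87-EV, grown in immunodeficient SCID mice. U87 is an established human glioblastoma cell line; the labels do not say what the added EV stands for. The labels put 3 arrays in a saline control group and 3 in a group treated with bevacizumab, an antibody that binds human vascular endothelial growth factor A. Per the labels' protocols, dosing began once tumours measured 150 to 200 mm3, the dose was 10 mg/kg into the peritoneum with 3 days between injections, and it went on until tumours were about 15 to 30 mm across. Each group started with 5 mice. The labels do not say that each array came from a separate mouse, so the p-values measure the spread between these arrays, which may be partly technical.

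The deposited table holds log2 expression values made with GCRMA, a method that corrects background by probe sequence, normalizes between arrays and summarises the probes of each probe set. The submitters' processing notes name GCOS 1.1.1.052 and GCRMA, with no version of the latter. That the scale is log2 was inferred from the values, which reach 15.99, and from GCRMA's usual output. The authors' values were used as deposited and no scanner files were used here, so the scale was not set against scanner signals. The array medians lay between 2.49 and 2.51. Between 33.4% and 34.3% of the probe sets of each array sat at the lowest value of the table, where values have no order. The number of arrays limits the precision. Array dates and processing batches were not given in the sources used here, so no batch could be tested. The probes were designed for human transcripts, and RNA of the mouse host was not separated from tumour RNA.

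Of the 54675 probe sets in the table, 62 were array controls. The platform annotation paired 41097 with 1 gene symbol and 1801 with several, and did not list 11777. For 41043 of the single-gene probe sets the gene identifier matched the reference gene table, which set the symbol, and 54 kept the symbol of the platform annotation. Probe sets with several genes or none were left out of the gene tests. For each of 19775 genes the probe set with the highest mean over the 6 arrays stood for the gene. Genes with a mean log2 value of at least 4 over all arrays were tested, which kept 10233 and left out 9542. The number of probe sets in the same direction is stated for genes past the threshold where they differed. No per-sample column was left unused.

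Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values and no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 counts as past the threshold. Log2 fold changes are bevacizumab minus control. Levels are means ± SD of 3 arrays. Where all 3 arrays of a group were under 4, the fold is a lower bound, computed from the brighter group's mean against 4 and written as at least that many fold. The ratio of 3' to 5' control probe sets for ACTB and GAPDH, a sign of RNA degradation, was compared by a two-sided exact permutation test, which cannot give a p under 0.1 with 3 arrays against 3.

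Before the data were examined, 30 gene lists and 10 lists of cell type markers were fixed, together with the design, the other settings to be tried and the rule for naming genes. The marker lists cover endothelial cells, mural cells, fibroblasts, macrophages, neutrophils, natural killer cells, red blood cells, adipocytes, keratinocytes and skeletal muscle. Lists with at least 5 measured members, 32 in all, were tested with camera at a preset correlation between genes of 0.01. Camera compares a list with all other genes. Some genes belong to more than 1 list, so the results of such lists are not independent. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, were run beside it. Genes were named by a fixed rule. It took the 12 highest and 12 lowest log2 fold changes among genes past the threshold with non-overlapping groups, up to 4 members of each list with the smallest p, and 15 genes fixed by name. Of those 15, 12 were tested, 2 were under the filter and 1 had no probe set analysed here. Members of small groups that fall outside this rule are named with the remark that they were chosen after their values were seen.

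The procedure was checked on simulated data, with 200 of 10233 genes changed in the comparison of bevacizumab with control. It recovered 22% of genes changed by 0.5 on the log2 scale, 62% of those changed by 1, 94% of those changed by 2 and all of those changed by 4, with 8 false calls among 147. The simulation changed far fewer genes than the 1950 called in the data, and its noise was independent between genes. These shares therefore do not give the sensitivity of the real fit.

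Results were recomputed with other settings: no filter on the mean, a stricter filter at 6, values under 4 set to 4, quantile normalization, median centring, the mean of a gene's probe sets, all probe sets tested singly, limma's trended robust prior, the replicate number as a block, unadjusted p-values, the 2 other list tests, and each array left out in turn. A pair of covariate fits, with the ACTB ratio or with the signal of the 18S ribosomal RNA control probe sets, was added after seeing the data.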

Results

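The study compared gene expression in U87-EV human glioblastoma xenografts from mice given bevacizumab with that in xenografts from mice given saline, 3 arrays per group. The series title frames the question as how blocking VEGF changes expression in the living tumour. The unit throughout is the deposited GCRMA value on the log2 scale. Of the 19775 genes with a probe set of their own, 10233 were bright enough to test. Array profiles correlated at 0.992 to 0.997 (Pearson, over all 54675 probe sets, which are not independent replicates) within groups and at 0.986 to 0.993 between groups. The first principal component held 68.1% of the variance and separated the groups, with all 3 controls on its negative side and all 3 bevacizumab arrays on its positive side.

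Bevacizumab tumours had higher expression of hypoxia-response, glycolysis and inflammatory cytokine genes, and lower expression of DNA replication, mitosis and respiratory chain genes. These lists passed with camera at a preset correlation but not with an estimated correlation (adjusted p = 0.277 for inflammatory and mitosis genes and 0.185 for the others). Among hypoxia genes 31 of 33 measured rose, by a median of 1.78 on the log2 scale, and none fell. Among DNA replication genes 24 of 28 fell and none rose, with a median of -0.88. Over all genes, 1950 passed the threshold, which is 19.1% of those tested; 930 were higher and 1020 lower after bevacizumab. A change of at least 2-fold was seen in 541 of these, 391 higher and 150 lower. The groups did not overlap in any of the 1950, and they did not overlap in 41.0% of all tested genes, against 10% by chance. At an unadjusted p under 0.05 there were 3664 genes. The count of 1950 dropped to 578, 558 and 897 when control 1, 2 or 3 was left out, and to 1075 without bevacizumab 2.

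The 3' to 5' differences, a sign of RNA quality, were higher on average after bevacizumab. For ACTB the groups overlapped, with 1.66 on control 3 and 1.64 on bevacizumab 3. The log2 difference between the 3' and 5' probe sets of ACTB was 1.38 ± 0.26 in controls and 1.81 ± 0.16 after bevacizumab (SD, n = 3 each; difference 0.43, exact permutation p = 0.2, smallest possible 0.1). For GAPDH it was -0.12 ± 0.02 and -0.02 ± 0.03 (difference 0.10, exact permutation p = 0.1, the smallest possible). With the ACTB difference as a covariate, 24 genes passed the threshold, among them 1 hypoxia gene and no member of the other 14 lists that passed the list test; their medians are given below with each group. The signal of 18S ribosomal RNA probe sets was 9.13 in controls and 8.20 after bevacizumab (n = 3 each; difference -0.93, exact permutation p = 0.2), and with it as a covariate 693 genes passed.

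MMP1, a collagenase, rose from 4.44 ± 1.26 to 10.23 ± 1.06 (SD, n = 3 each). This is a log2 fold change of 5.79 (SE 0.77, limma adjusted p = 0.0078), or 55.5-fold, and it was 5.61 with values under 4 set to 4. Genes with values under 4 are not ranked here by size. All controls were under 4 for ACKR3, IL1RN, MAP3K8, CXCL13 and SPINK1. ACKR3, a scavenger receptor for the chemokine CXCL12, rose at least 14.3-fold, and IL1RN, the interleukin 1 receptor antagonist, at least 12.5-fold. The bevacizumab arrays of IL1RN ran from 6.33 to 8.85, so its bound depends on which arrays are averaged. TNFRSF11B, which encodes the decoy receptor osteoprotegerin, rose by 4.70 (SE 0.34, adjusted p = 0.00196). STC2, a secreted glycoprotein with 2 controls under 4, rose by 3.94 with values under 4 set to 4 (4.49 as deposited). The cytokine gene IL6 rose by 4.44 and the stress transcription factor gene ATF3 by 4.19. The protease gene ADAMTS5 rose by 4.06. The interleukin 7 receptor gene IL7R, also with 2 controls under 4, rose by 3.17 with values under 4 set to 4 (3.86 as deposited). The kinase gene MAP3K8 rose at least 5.50-fold, with SDs of 0.13 and 0.12 in the 2 groups. The B cell chemokine gene CXCL13 (at least 7.84-fold, adjusted p = 0.0451) and SPINK1, a trypsin inhibitor gene (at least 5.64-fold, adjusted p = 0.0155), varied most. On bevacizumab 1, 2 and 3 CXCL13 read 4.66, 6.46 and 9.79, and SPINK1 5.92, 5.40 and 8.16, so bevacizumab 3 raises both bounds. CXCL13 lost its call without any 1 of the controls or bevacizumab 2, and SPINK1 without any 1 of the controls.

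Of the 12 genes named for a decrease, 9 were under 4 on every bevacizumab array, so their sizes are lower bounds. WFDC1, a secreted protein gene, was at least 9.23-fold lower (7.21 ± 0.55 in controls and 2.40 ± 0.22 after bevacizumab, SD, n = 3 each; limma adjusted p = 0.00158). ENPEP, an aminopeptidase found on pericytes among other cells, was at least 9.85-fold lower, and the small matrix proteoglycan genes EPYC and OGN at least 7.84-fold and 7.12-fold lower. CRYGS, a crystallin gene, was at least 7.90-fold lower, FRZB, a secreted Wnt antagonist, at least 5.01-fold, and MMP9, a gelatinase, at least 4.16-fold. HEYL, a Notch target gene, was at least 3.91-fold lower and SLC40A1, the iron exporter ferroportin, at least 2.70-fold. GUCY1A1, a subunit of the nitric oxide receptor, fell by 2.92 (SE 0.23, adjusted p = 0.00221), CCDC102B by 2.86 and the pericyte marker RGS5 by 2.85, the last on 5 of its 5 probe sets. Of the 24 genes named for the size of their change, 22 passed the threshold in each of the 6 fits that left out an array.

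Among the genes fixed by name, VEGFA itself, the target of the antibody, rose from 12.68 ± 0.18 to 14.08 ± 0.27 (SD, n = 3 each), a log2 fold change of 1.40 (SE 0.17, limma adjusted p = 0.00609) on 4 of 4 probe sets. NDRG1, a hypoxia-induced gene, rose by 3.22 (SE 0.22, adjusted p = 0.00184). The glucose transporter gene SLC2A1 rose by 3.07, hexokinase 2 (HK2) by 2.68, adrenomedullin (ADM) by 2.27 and the mitophagy gene BNIP3 by 1.77. MKI67, a marker of cycling cells, fell by 1.03 (SE 0.18, adjusted p = 0.0144), a call that was lost without any 1 of the controls. The fatty acid binding protein gene FABP3 had a difference of 3.38 with an SE of 1.31 and an adjusted p of 0.122. Its arrays ran from 3.94 to 6.82 in controls and from 6.80 to 11.15 after bevacizumab, so the groups overlapped. FABP7 (1.02, adjusted p = 0.0634), EGLN3 (0.89, adjusted p = 0.0700), the glycogen phosphorylase gene PYGL (0.60, adjusted p = 0.111) and the lactate dehydrogenase gene LDHA (0.18, adjusted p = 0.171) did not pass either. The lipid droplet gene PLIN2 lay between 2.24 and 2.87 on its 2 probe sets on every array, and the Notch ligand gene DLL4 between 3.62 and 3.69, so neither was tested.

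**Figure D1:**
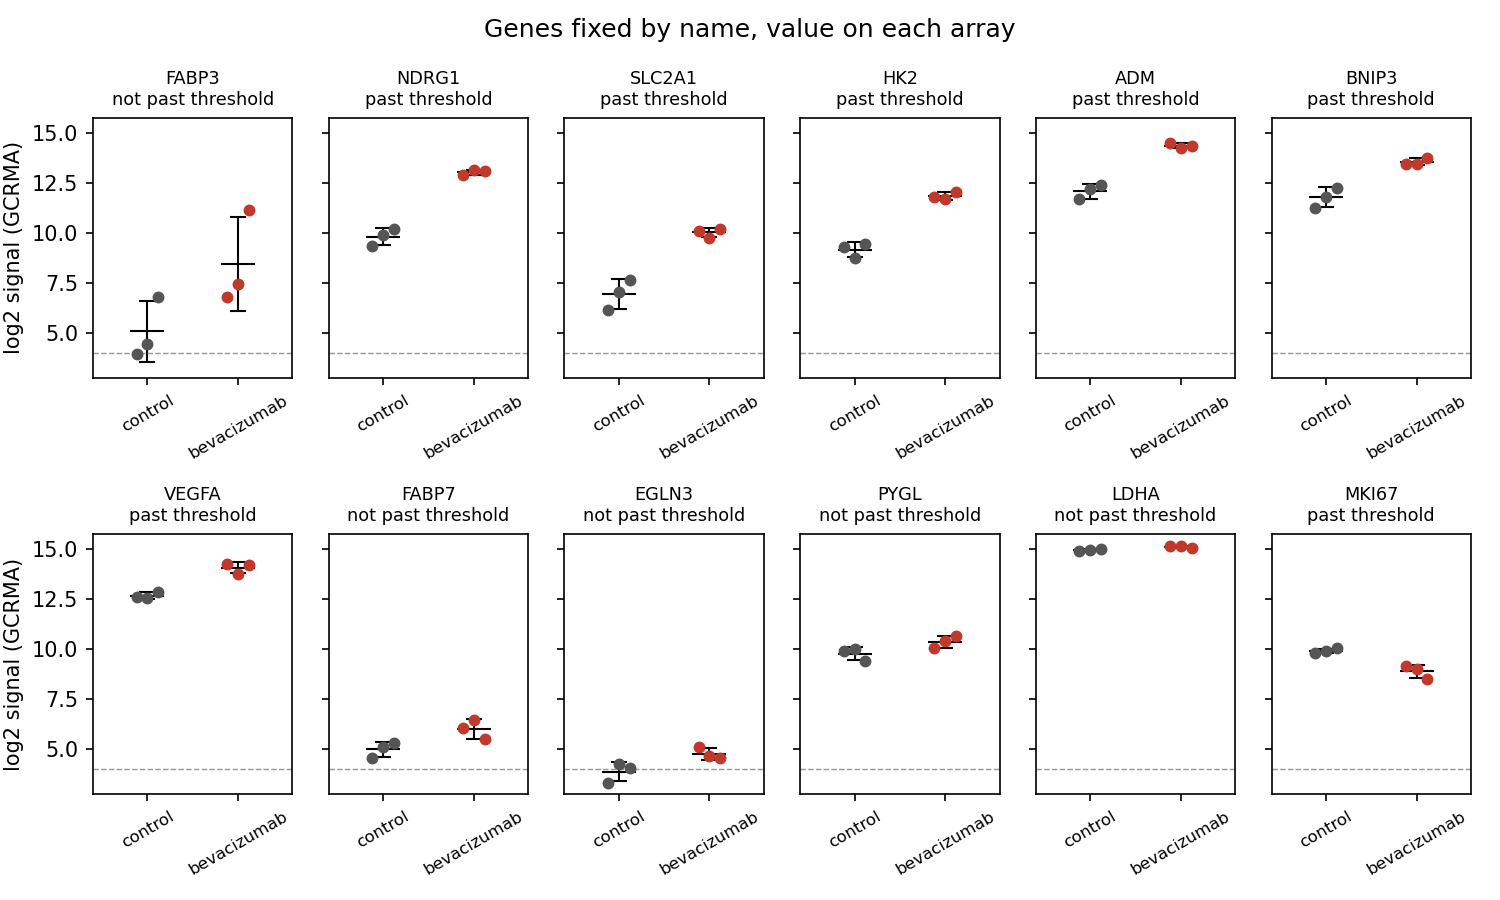
The log2 GCRMA signal on each array for the 12 tested genes fixed by name; points are arrays, horizontal bars are means and error bars are SD (n = 3 per group), and the dashed line marks 4. NDRG1, SLC2A1, HK2, ADM, BNIP3 and VEGFA are higher and MKI67 lower after bevacizumab past the threshold, and FABP3 reaches 11.15 on 1 bevacizumab array.

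Genes of the hypoxia list, which are induced when oxygen is short, rose nearly throughout. Of 33 measured, 31 rose and none fell, 32 rose when adjusted over the list alone, and the median was 1.78 (camera adjusted p = 4.6e-23; adjusted p = 0.185 with an estimated correlation). Besides NDRG1, the ankyrin repeat gene ANKRD37 rose by 2.27, the mTOR inhibitor gene DDIT4 by 1.61 and the collagen hydroxylase gene PLOD2 by 1.17. EGLN3 (0.89 on the brighter probe set, 2.72 on its other) and ANKZF1 (0.09, named after its value was seen) did not pass. With the ACTB difference as a covariate the median was 1.66.

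Glucose handling rose with it. Of 21 glycolysis genes 13 rose and none fell, 14 rose when adjusted over the list alone, and the median was 0.61 (camera adjusted p = 2.6e-09; adjusted p = 0.185 with an estimated correlation; median 0.73 with the ACTB covariate). The neuronal-type glucose transporter gene SLC2A3 rose by 3.09, HK2 by 2.68, the aldolase gene ALDOC by 2.43 and PFKFB4, which makes an activator of phosphofructokinase, by 1.83. SLC2A3, ALDOC and PFKFB4 also belong to the hypoxia list, as do SLC2A1, PFKFB3, ENO2 and PDK1 of the glycolysis list. Without control 1, 8 glycolysis genes passed. In the glycogen list 6 of 14 genes rose, 1 fell and 7 did not pass, with 7 higher and 3 lower when adjusted over the list alone (median 0.44, camera adjusted p = 0.0118; adjusted p = 0.251 with an estimated correlation; median 0.51 with the ACTB covariate). The regulatory subunit genes PPP1R3B and PPP1R3C, which steer a phosphatase to glycogen, rose 4.68-fold and 3.68-fold. The branching enzyme gene GBE1 rose 2.06-fold and the glycogen synthase gene GYS1 by 2.03 on the log2 scale, the last with a call that was lost without any 1 of the controls or bevacizumab 2. GYG1, which primes glycogen chains, fell by 0.44 (named after its value was seen). Leaving out any 1 of the controls or bevacizumab 2 left 3 glycogen genes higher, and with a filter at 6 the list did not pass (adjusted p = 0.106; 0.00423 to 0.106 over its alternatives). Without bevacizumab 3, 3 glycogen genes were lower, and without the filter on dim genes the glycogen median was 0.23.

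Cell cycle genes were lower. Of 28 DNA replication genes 24 fell and none rose, with 25 lower when adjusted over the list alone (median -0.88, camera adjusted p = 6.4e-14; adjusted p = 0.185 with an estimated correlation; median -0.97 with the ACTB covariate). MCM10, which helps to start replication, fell by 1.42 (SE 0.14, limma adjusted p = 0.00424), CDC45 by 1.34 and the origin licensing gene CDC6 by 1.26. The helicase subunit gene MCM7 was 2.08-fold lower (adjusted p = 0.00207). Without control 1 or control 2, 14 replication genes passed. Of 24 mitosis genes 18 fell and none rose, with 21 lower when adjusted over the list alone (median -0.71, camera adjusted p = 2.5e-10; adjusted p = 0.277 with an estimated correlation; median -0.88 with the ACTB covariate). The kinase gene AURKB fell by 1.11 (SE 0.09, adjusted p = 0.00225), CCNB1, encoding cyclin B1, by 0.96 and the spindle checkpoint gene BUB1 by 0.94; NEK2 fell by 0.86, and lost its call without control 1 or control 2. The mitosis genes past the threshold without control 1, 2 or 3 numbered 3, 3 and 5, and without bevacizumab 2 they numbered 9.

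Ribosome biogenesis genes were lower by less. Of 17 measured, 5 fell and none rose, with 6 lower when adjusted over the list alone (median -0.28, camera adjusted p = 0.00223; adjusted p = 0.185 with an estimated correlation; median -0.38 with the ACTB covariate). RRS1 fell by 0.76 (SE 0.09, limma adjusted p = 0.0067), WDR12 by 0.61, NOP2 by 0.61, the RNA polymerase I subunit gene POLR1B by 0.64 and NOLC1, named after its value was seen, by 0.36. Of the probe sets, 2 of 3 for WDR12 and 3 of 4 for POLR1B ran in that direction. Leaving out control 1, 2 or 3 gave 2, 1 and 1 ribosome biogenesis genes past the threshold, and without bevacizumab 2 or 3 there were 2 and 3.

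Mitochondrial genes were modestly lower. Of 31 oxidative phosphorylation genes 10 fell, none rose, and 18 fell when adjusted over the list alone (median -0.32, camera adjusted p = 2.0e-08; adjusted p = 0.185 with an estimated correlation; median -0.36 with the ACTB covariate). The complex III gene UQCRC2 fell by 0.68 (SE 0.10, limma adjusted p = 0.00933), the complex I genes NDUFA9 and NDUFS3 by 0.64 and 0.53, and the ATP synthase gene ATP5F1A by 0.64. Without control 1, 2 or 3 there were 2, 2 and 3 such genes past the threshold, and without bevacizumab 2 there were 6. Of 18 fatty acid oxidation genes 7 fell and none rose, with 7 lower and 1 higher when adjusted over the list alone (median -0.25, camera adjusted p = 0.0112; adjusted p = 0.282 with an estimated correlation; median -0.36 with the ACTB covariate). ECI1 fell by 0.63, the trifunctional protein gene HADHA by 0.51 and the electron transfer flavoprotein genes ETFB and ETFA by 0.44 and 0.43. Fits without control 1, 2 or 3 had 0, 1 and 0 fatty acid oxidation genes past the threshold, and without bevacizumab 2 or 3 there were 1 and 2, the latter with 1 gene higher.

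Inflammatory genes rose steeply. Of 17 cytokines and NF-kB targets 10 rose and none fell, with 13 higher when adjusted over the list alone (median 1.45, camera adjusted p = 1.6e-07; adjusted p = 0.277 with an estimated correlation; median 1.77 with the ACTB covariate). IL6 rose from 6.27 ± 1.02 to 10.71 ± 0.69 (SD, n = 3 each; limma adjusted p = 0.0074). The cyclooxygenase gene PTGS2 rose by 3.77 and TNFAIP3, a feedback inhibitor of NF-kB, by 2.88. The adhesion molecule gene ICAM1 rose at least 3.06-fold, with 1 of its 2 probe sets in that direction. Fits without control 1, 2 or 3 had 5, 5 and 6 such genes past the threshold. Interferon response genes went the other way, with 4 of 17 lower, none higher, and 6 lower when adjusted over the list alone (median -0.57, camera adjusted p = 0.00306; adjusted p = 0.299 with an estimated correlation; median -0.53 with the ACTB covariate). The antiviral gene IFIT1 fell by 1.27, IFI44 by 0.94, the ubiquitin-like gene ISG15 by 0.78 and the RNA sensor gene RIGI by 0.53, a call lost in all 6 fits that left out an array. ISG15 alone of these passed in each of those fits, and without control 1 or control 3 there was 1 interferon gene past the threshold. The interferon median was -0.37 without the filter on dim genes.

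Genes of invasion and matrix changed in both directions. Among proteases and their inhibitors 7 of 22 rose and 1, MMP9, fell, with 14 higher and 2 lower when adjusted over the list alone (median 0.50, camera adjusted p = 3.3e-04; adjusted p = 0.185 with an estimated correlation; median 0.58 with the ACTB covariate). After MMP1, the protease genes ADAMTS1 and CTSB rose by 1.39 and 0.55. Without control 1, 2 or 3 there were 3, 2 and 3 genes higher, and without bevacizumab 1 there were 2 lower. Among collagens and matrix genes 8 of 25 rose and 4 fell, with 11 higher and 4 lower when adjusted over the list alone (median 0.24, camera adjusted p = 0.00343; adjusted p = 0.299 with an estimated correlation; median 0.43 with the ACTB covariate). The crosslinking enzyme genes LOX and LOXL2 rose by 2.85 and 2.21, PLOD2 by 1.17 and the fibrillin gene FBN1 by 0.86. LOX and PLOD2 also belong to the hypoxia list, as do P4HA1 and P4HA2 of the matrix list. The 4 that fell were the basement membrane collagen genes COL4A1 (-2.45) and COL4A2 (-1.64), POSTN (-1.16) and COL3A1 (-0.84), of which all but COL3A1 were named after their values were seen. Without control 1, 2 or 3 there were 0, 0 and 1 matrix genes lower, and without bevacizumab 2 there were 2.

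Mesenchymal glioblastoma markers were higher, with 9 of 15 up, none down, and 10 higher when adjusted over the list alone (median 0.49, camera adjusted p = 9.5e-06; adjusted p = 0.185 with an estimated correlation; median 0.44 with the ACTB covariate). The transcription factor genes BHLHE40, CEBPB and STAT3 rose by 1.51, 1.22 and 0.86, and TGFBI by 1.35. BHLHE40 also belongs to the hypoxia list. Without control 1 or control 2 there were 4 such genes past the threshold, and without bevacizumab 2 there were 5. Among angiogenic factors and receptors 7 of 17 rose and 2 fell, with 9 higher and 2 lower when adjusted over the list alone (median 0.43, camera adjusted p = 0.00715; adjusted p = 0.185 with an estimated correlation; median 0.49 with the ACTB covariate). Without the filter on dim genes the median of all 26 angiogenic genes was 0.07, with 4 higher and 1 lower. Besides VEGFA and ADM, which also belong to the hypoxia list, the fibroblast growth factor gene FGF2 rose by 2.22. ANGPT2, a ligand of the endothelial receptor TEK, was at least 2.41-fold lower, and THBS1, an angiogenesis inhibitor gene named after its value was seen, fell by 1.26. Without control 1, control 3 or bevacizumab 2 only 1 of this pair passed.

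In the amino acid and integrated stress response list 10 of 25 genes rose and 3 fell, with 14 higher and 3 lower when adjusted over the list alone (median 0.44, camera adjusted p = 0.00485; adjusted p = 0.299 with an estimated correlation; median 0.53 with the ACTB covariate). The stress transcription factor gene ATF3 rose by 4.19, VLDLR by 1.41, CEBPB by 1.22 and the pseudokinase gene TRIB3 by 1.14. The 3 that fell, named after their values were seen, were the serine and one-carbon pathway genes PHGDH (-0.90), PSAT1 (-0.56) and SHMT2 (-0.36). Leaving out control 1 or control 2 left 6 genes higher, and 0 and 1 lower.

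**Figure D2:**
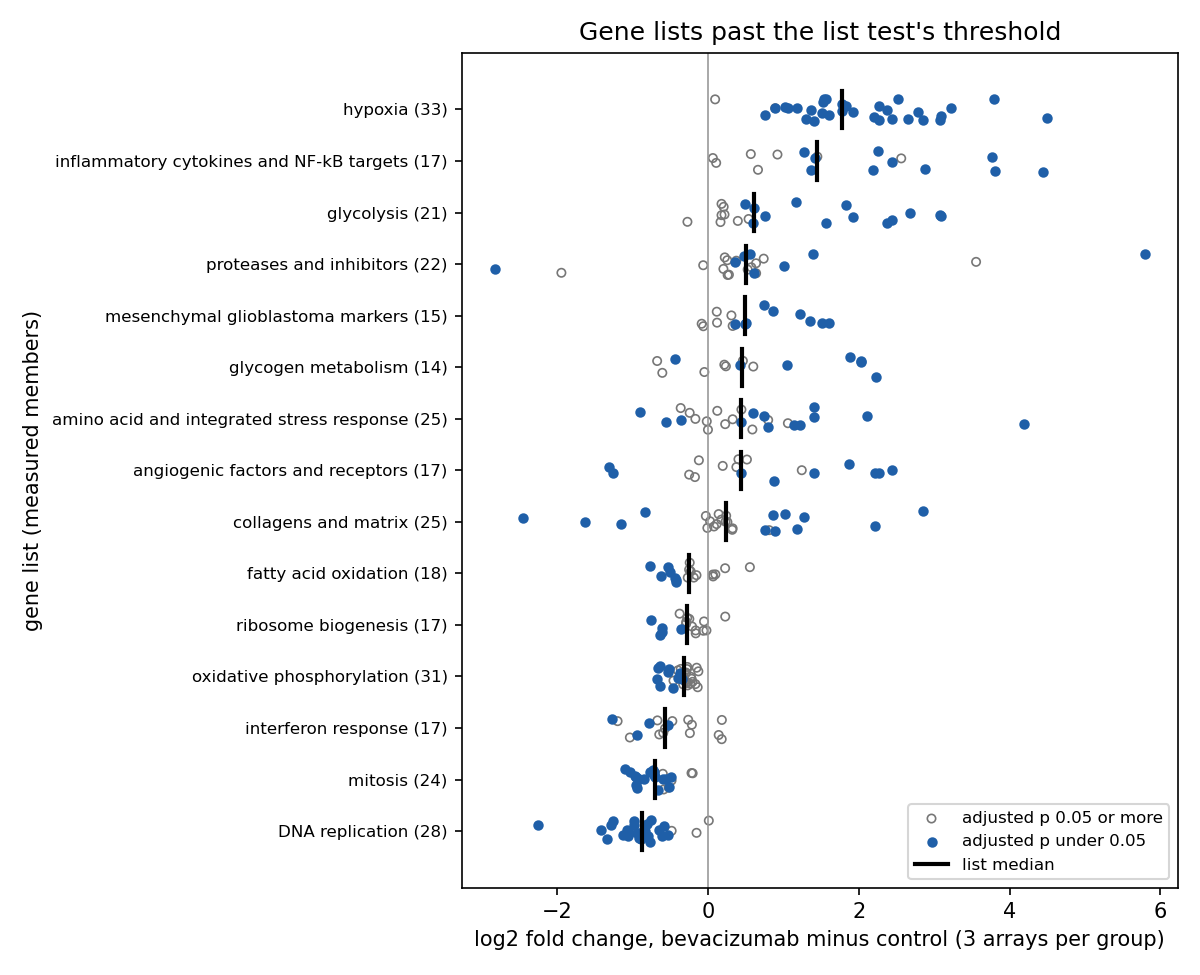
Log2 fold changes (bevacizumab minus control, 3 arrays per group) of every measured member of the 15 lists past the list test's threshold; filled points passed the gene test, open points did not, and black bars are list medians. List medians run from -0.88 for DNA replication to 1.78 for hypoxia.

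In all, 15 of the 32 lists tested passed with camera at its preset correlation, 9 higher and 6 lower. None passed with an estimated correlation, where 8 had an unadjusted p under 0.05 and the smallest adjusted p was 0.185. By fry 25 passed. For proteases the estimated correlation was 0.0102, about the preset 0.01, yet camera's adjusted p went from 3.3e-04 to 0.185. Not passing in that form of the test therefore does not show that correlation between genes accounts for a list. Setting values under 4 to 4 moved the median of no list that passed. Without the filter on dim genes, 19775 genes entered both the fit and the adjustment. Fewer members then passed: 25 hypoxia, 7 glycolysis, 2 inflammatory, 2 protease, 2 amino acid and 3 glycogen genes were higher. Lower were 13 DNA replication, 3 mitosis, 4 oxidative phosphorylation, 1 ribosome biogenesis, 1 interferon, 0 fatty acid oxidation, 0 matrix and 1 amino acid gene.

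Several lists did not pass although members changed, and of these fatty acid synthesis, cholesterol synthesis and immediate early genes passed in some alternatives. In fatty acid synthesis the desaturase gene SCD rose by 2.41, SREBF1, a lipid synthesis regulator, by 1.93 and the carboxylase gene ACACA by 0.46 on 1 of its 2 probe sets, with 9 of 12 not passing (list adjusted p = 0.0707; 0.0347 to 0.128 over its alternatives); ACACA passed in 1 of the 6 fits that left out an array. In fatty acid uptake the lipid droplet gene HILPDA, also in the hypoxia list, rose by 3.79 and the lipoprotein receptor gene VLDLR by 1.41. FABP5 and G0S2 fell by 0.84 and 0.54 (list adjusted p = 0.121). The calls of FABP5 and G0S2 were both lost without any 1 of the controls or bevacizumab 2. In cholesterol synthesis 6 of 15 rose, such as MSMO1 by 0.76 and INSIG1 by 0.75, and SC5D fell by 0.56 (list adjusted p = 0.0923; 0.0381 to 0.499 over its alternatives). None of the 6 rose past the threshold without control 1 or control 2, and 3, 3, 2 and 1 cholesterol genes did without control 3, bevacizumab 1, bevacizumab 2 and bevacizumab 3; MSMO1 passed in 1 of these 6 fits, and INSIG1 and SC5D each in 2. In the immediate early list 5 of 13 rose, such as IER3 by 2.67, JUNB by 0.94 and JUN by 0.66, and IER2 and EGR3 fell by 0.73 and 1.17, EGR3 being named after its value was seen (list adjusted p = 0.0851; 0.0233 to 0.169 over its alternatives). The immediate early genes higher numbered 2 without control 1 or control 2 and 3 without control 3 or bevacizumab 2, and those lower numbered 0 without control 1 and 1 without control 3, bevacizumab 2 or bevacizumab 3. Of 13 Notch pathway genes HEY1 was 2.84-fold lower (adjusted p = 0.00504) and HEYL fell as given above (list adjusted p = 0.105).

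For TGF-beta targets the list median was 0.14 (-0.13 to 0.28 over its alternatives), the mean -0.16 and camera's direction lower (adjusted p = 0.775). There ID2 and TGFBI rose by 1.66 and 1.35, while ID1 and ID3, inhibitors of differentiation, fell by 1.86 and 1.48; THBS1 and CCN2, which also fell, were named after their values were seen, and 2 TGF-beta targets were lower without control 1. The p53 target genes TIGAR, PPM1D and FAS fell by 1.07, 0.83 and 0.52, with 14 of 17 not passing (list adjusted p = 0.138). Only TIGAR of these passed without any 1 of the controls or bevacizumab 2. In autophagy GABARAPL1, ATG14, SQSTM1 and MAP1LC3B rose by 1.34, 0.71, 0.58 and 0.48, with 16 of 20 not passing (list adjusted p = 0.167). Only GABARAPL1 of these passed without any 1 of the controls or bevacizumab 2, and 7 autophagy genes were higher without bevacizumab 1. Among apoptosis regulators BNIP3 and BNIP3L, which also belong to the hypoxia list, rose by 1.77 and 1.30 (list adjusted p = 0.334). In pH regulation the carbonic anhydrase gene CA12, also in the hypoxia list, rose by 2.20. The bicarbonate transporter gene SLC4A4 rose by 1.25 (list adjusted p = 0.334), a call held only without bevacizumab 1. Of the NRF2 and pentose phosphate list FTL rose by 0.65, and NQO1 and GCLM (on 2 of 3 probe sets) fell by 0.86 and 0.45 (list adjusted p = 0.398), and all 3 lost their call without any 1 of the controls. In the endoplasmic reticulum stress list PDIA3 (on 2 of 3 probe sets) and DNAJB9 rose by 0.42 and 0.66 and SDF2L1 fell by 0.50 (list adjusted p = 0.732), but PDIA3 and DNAJB9 passed in 0 of the 6 fits that left out an array and SDF2L1 in 1. The stem cell marker NES fell by 1.18 in a glial list of 5 whose median was 0.28 (list adjusted p = 0.895). That median ran from -0.13 to 0.42 over the alternatives, the lowest with the ACTB covariate. No metallothionein list member passed (0 of 8 with limma; list adjusted p = 0.775, median 0.06, mean -0.13, fry's adjusted p = 0.793). The metallothionein median ran from -0.15 to 0.09 over the alternatives. In some of them 1 member was lower, for instance with a filter at 6, values under 4 set to 4 or quantile normalization. Of 9 reference genes TFRC and GUSB (on 1 of 2 probe sets) rose by 0.99 and 0.55 and SDHA fell by 0.47 (list adjusted p = 0.726); GUSB passed in 0 of the 6 fits that left out an array, and SDHA lost its call without any 1 of the controls.

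Markers of other cells moved apart. Of 8 measured mural and smooth muscle genes, RGS5 fell by 2.85, the contractile genes TAGLN (-2.16, SE 0.12, limma adjusted p = 0.0014) and ACTA2 (-1.79, SE 0.18, adjusted p = 0.00407) fell too, and 5 did not pass, among them PDGFRB with 0.30. The mural list did not pass (median -0.18, adjusted p = 0.0923), but did without bevacizumab 3 (median -1.39, adjusted p = 0.00472; 0.00472 to 0.398 over its alternatives). Its median was 0.05 without bevacizumab 1 and 0.24 with the ACTB covariate. Of 9 fibroblast genes PDPN, which encodes podoplanin, rose by 3.82 (SE 0.12, adjusted p = 2.3e-04) and DPT by 2.26, while COL3A1 fell by 0.84 (list adjusted p = 0.151; 0.0228 to 0.358 over its alternatives, the lowest with the ACTB covariate). DPT lost its call without control 1, and COL3A1 without any 1 of the controls or bevacizumab 3. The endothelial genes ENG (0.57), PECAM1 (0.18) and TEK (-0.03) did not pass, and the other 11 endothelial markers in the table were under the filter. Among macrophage markers ADGRE1 fell by 0.92, a call lost without any 1 of the controls or bevacizumab 2, AIF1 had a difference of -0.14 and 12 were under the filter. The neutrophil marker FPR1 (-0.62), the natural killer marker PRF1 (0.83) and the keratinocyte markers SFN (0.26) and KRT10 (-0.02) did not pass. TNNT3 of skeletal muscle rose by 1.07, but was dim, at 4.26 in controls and 5.33 after bevacizumab. Bright enough to test were 1 of 8 skeletal muscle, 1 of 8 neutrophil, 1 of 6 natural killer and 2 of 7 keratinocyte markers in the table. No red blood cell or adipocyte marker was bright enough to test. The PRF1 difference came from bevacizumab 3, at 7.99 against 5.56 and 5.50 on bevacizumab 1 and 2. Controls for SFN ran from 4.85 to 6.28.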

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

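Among the tests in this part, the one on loss of host mural cells was chosen after the result was seen, as were the covariate fits. A signal appeared in data that the comparison of genes did not use, the 13522 probe sets with no single gene name. Of 3198 bright enough to test, 56 were higher and 42 lower after bevacizumab past the threshold.

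The hypoxia genes rose together while the ACTB 3' to 5' difference, a sign of RNA quality, was also higher on average after bevacizumab. With that difference as a covariate, the median log2 fold change of the list was 1.66, against 1.78 without it, and the lower quartile of its members was 1.19. This argues against RNA quality, as measured by ACTB, as the whole cause. Only 1 of the 33 genes then passed the threshold, so the gene calls were not kept: the median standard error went from 0.20 to 0.27, larger in 32 of the 33, and 31 had an unadjusted p under 0.05. With the 18S signal as a covariate the median was 1.86 and 29 genes passed, which argues against carried-over ribosomal RNA. The GAPDH 3' to 5' difference ran from -0.14 to -0.11 in controls and from -0.06 to 0.01 after bevacizumab. It was not used as a covariate, so RNA quality as measured by GAPDH stays open. An effect of bevacizumab, or of tumour size or necrosis at collection, stays open and was not tested.

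Mural genes such as RGS5 and ENPEP fell strongly, and one candidate explanation is a loss of mouse mural cells whose RNA binds human probes. In an extended list, 12 of 27 measured members fell past the threshold and none rose, which is short of a general fall. In other members, such as PDGFRB (0.30), the 95% interval excluded a fall of 1 on the log2 scale. The changes of such members ran from -0.32 (GJC1) to 0.75 (ITGA7). However, only 4 of them were dim in controls: ANPEP, COX4I2, COXFA4L2 and CSPG4, with control means from 4.02 to 7.56. The rest were brighter, with control means from 9.34 (ITGA7) to 13.93 (CALD1). With so few dim members, a host cell loss and a change within cells cannot be told apart. The 12 that fell were partly bright too, with control means from 5.67 (KCNJ8) to 12.76 (ACTA2). Of 14 endothelial markers in the table only 3 were bright enough to test. How much host RNA these probes read was not measured. With the ACTB covariate the median of the 12 that fell was -2.15, against -2.11 without it. This argues against RNA quality, as measured by ACTB, as the whole cause for these 12 only. They were chosen for having fallen, and 1 still passed as the median standard error went from 0.20 to 0.35. Over all 27 the median went from -0.64 to -0.43. The GAPDH difference was not used as a covariate here either.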

How the results depend on the processing

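The covariate fits in this part were chosen after the data were seen. Across the alternatives, none of the 126 named genes and none of the 15 lists past the threshold turned its direction. The 1950 called genes kept theirs in every fit but 2: 1949 did with quantile normalization, and with the mean of a gene's probe sets 1834 of the 1840 tested did, so 6 turned. In several fits a gene could not turn. Leaving out an array cannot turn a gene whose groups do not overlap, as held for all 1950. Changed filters, the trended prior and the replicate block leave each gene's log2 fold change as it was. With a stricter filter, values under 4 set to 4, median centring, quantile normalization, single probe sets or a trended prior, the count of genes stayed within 1.5 times. Without the filter on dim genes, there were 598 genes past the threshold: 267 genes higher after bevacizumab, 331 genes lower after bevacizumab, and 221 genes past the threshold with at least a 2-fold change, where 19775 genes were tested. With the mean of a gene's probe sets 357 genes passed with at least a 2-fold change; the cause was not tested. Leaving out each array in turn gave 558 to 2074 genes past the threshold, 296 to 1140 higher, 262 to 934 lower and 306 to 675 with at least a 2-fold change, on fewer samples. The lowest total came without control 2, and 578, 897 and 1075 came without control 1, control 3 and bevacizumab 2. Of the 126 named genes, 44 lost their call in 1 or more of these 6 fits. With the ACTB covariate 24 genes passed (13 higher, 11 lower, 24 with at least a 2-fold change); standard errors were larger in 9994 of 10233 genes, with a median of 0.20 against 0.14, on fewer degrees of freedom. With the 18S covariate there were 693 (410 higher, 283 lower, 354 with at least a 2-fold change), and the cause of that drop was not tested. At an unadjusted p under 0.05, 3664 genes passed. Of the lists, 0 passed with an estimated correlation and 25 by fry.

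With the replicate number as a block (replicate block), 904 genes passed, 568 genes higher after bevacizumab and 336 genes lower after bevacizumab. No pairing by number was seen: the deviations of same-numbered arrays correlated at -0.05, -0.01 and -0.05. Of the 6 arrays, 0 correlated best with its own number. The positive values between groups were control 3 with bevacizumab 1 (0.23), control 1 with bevacizumab 2 (0.21) and control 2 with bevacizumab 3 (0.18). With so few arrays, these values can neither show nor exclude a pairing. Higher genes made up 62.8% of the calls with the block, against 47.7% without it. Of the 126 named genes past the threshold, 31 lost their call with the block, as did 0 of the 15 lists. The 3' to 5' differences ranged from 0.31 to 0.57 for ACTB and from 0.08 to 0.11 for GAPDH with each array left out. Near the lowest table value, signal over background limits the size of a fold.

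The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split alone (1 of 10) reached 1950 genes, 930 higher, 1020 lower and 541 with at least a 2-fold change, with 0 as the highest of the others for each. Every other split puts both treatments on each side, so a treatment difference enters the spread within a side and lowers the gene counts. The 0 is therefore not a measure of chance. The real split gave 15 lists and the others 4 to 13.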

Other observations

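Of the tests in this part, that on complement was chosen after the result was seen. List p-values here were adjusted over the lists of this part alone, so they are not comparable with those adjusted over the 32 lists above. The lists of this part were not among the 40 fixed at the start. Complement genes, which encode proteins of innate defence in serum and tissue, were higher after bevacizumab. Of 10 measured, 6 rose past the threshold and none fell, with a median log2 fold change of 2.08 (camera adjusted p = 6.2e-05; adjusted p = 0.0629 with an estimated correlation; fry adjusted p = 8.2e-05). The protease genes C1R and C1S rose by 3.22 and 2.68, the factor B gene CFB by 2.82 and C3 by 2.78. The hypothesis that Jumonji histone demethylases, which need oxygen, were higher as a group was tested on 15 genes. Of these 4 rose and none fell, with a median of 0.30 (camera adjusted p = 0.0162; adjusted p = 0.138 with an estimated correlation; fry adjusted p = 0.00693). They were KDM7A (1.70, on 1 of 2 probe sets), KDM3A (1.52), KDM4B (1.22) and KDM5B (1.14), and KDM3A also belongs to the hypoxia list.

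A list of homologous recombination and Fanconi pathway genes, which repair DNA breaks and crosslinks, was tested for lower expression. Of 17 measured, 12 fell and none rose, with a median of -0.79 (camera adjusted p = 3.7e-06; adjusted p = 0.138 with an estimated correlation; fry adjusted p = 0.00372). UBE2T fell by 1.17, EXO1 by 1.24, CHEK1 by 0.90 and RAD51C by 0.88. Many of these genes are also expressed mainly in cycling cells, and that share was not separated here. Mitochondrial ribosome genes were lower too, with 9 of 30 past the threshold and none higher (median -0.31, camera adjusted p = 3.7e-06; adjusted p = 0.138 with an estimated correlation; fry adjusted p = 0.00466), led by MRPL15, which fell by 0.72. In the citric acid cycle 5 of 15 genes fell and none rose, with a median of -0.24 (camera adjusted p = 0.00305; adjusted p = 0.138 with an estimated correlation; fry adjusted p = 0.00466). They were IDH3B (-0.93), IDH3A (-0.74), PDHA1 (-0.64), SUCLG1 (-0.62) and SDHA (-0.47), the last also in the oxidative phosphorylation and reference lists.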
